A study of Drosophila melanogaster with 2 samples.

How the data were processed

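Transcription factor ChIP-seq was done by the authors on whole Drosophila melanogaster embryos aged 0 to 24 h that carried an eGFP-tagged bbx transgene. Per the labels, an anti-GFP antibody was used, chromatin was sonicated to fragments of 200 to 800 bp, and the 2 samples are biological replicates of 1 group. No comparison between groups exists, and no untagged sample was used here.

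The authors called peaks against a control alignment on the dm6 assembly and compared them by the irreproducible discovery rate (IDR), per the deposited text files. The peak caller, the aligner and their settings are not given in the sources used here. The deposited peak signal is the authors' value for the enrichment of each peak, in pooled reads or in 1 replicate, and its scaling is not given in the sources used here. The deposited score is the authors' IDR score, a rescaled global IDR. The -log10 values deposited beside it are, per the layout of the authors' files, those of the caller's q and of the IDR. Thresholded lists held peaks with an IDR of at most 0.01, and were derived with 1 further file whose purpose is not given in the sources used here. The conservative thresholded set, which rests on the comparison of the 2 replicates, was the main set. The series' other thresholded set, the ranked lists and the lists of each replicate served the comparisons and alternatives. Each conservative peak carries the signal of both replicates in a first and a second column, which were not assigned to replicate numbers. No read totals were given, so the depth per sample is unknown. Intervals of shares are 95% Wilson intervals, those of the DRE folds are 95% intervals from 1000 bootstrap draws of peaks, and all cover counting error only, as does the limit of 3 counts given for a count of 0.

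Peak ends lay within the chromosome lengths of release 6 of the genome, the dm6 coordinates. Genes and transcription start sites (TSSs) came from the Ensembl annotation, with transposable element genes left out, and microRNA genes were taken by their precursor transcripts. Positions are 1-based, and 2L, 2R, 3L, 3R, 4, X and Y were used. A gene counted as occupied when a summit lay within 500 bp of 1 of its TSSs. Each summit was put into 1 class, in the order promoter (within 500 bp of a TSS), 5' UTR, coding exon, 3' UTR, other exon, intron and intergenic.

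Overlap of the replicates (at least 1 bp) was tested with 1000 circular shifts of the replicate 2 peaks, and the location of summits with 1000 draws of random positions on the same chromosomes, for which the smallest two-sided p is 0.002. Signal at promoters and elsewhere was compared by the difference of medians with 100000 resamples. Peaks per chromosome were tested with exact binomial tests against length without unknown bases. The 29 gene lists were tested with Fisher's exact test against all other protein-coding genes, or all other genes for the RNA lists. The 30 motifs and all 8-base sequences, with reverse complements joined, were tested with exact sign tests. Each window of 100 bp to either side of a summit was paired with a window 1000 bp away on a random side. All tests were two-sided with a threshold of 0.05 after Benjamini-Hochberg adjustment within each family. Genes and peaks are not independent replicates, since neighbouring genes can share a summit. The methods were also tested on simulated data. With genes marked as occupied at random and independently of each other, 3 of 3 planted gene lists and 0 of 26 others passed. That simulation had no shared summits, so it does not test the list p-values where neighbouring genes share one. With 4000 simulated peaks, 0 of 30 motifs passed where none was planted. Those peaks lay at random positions, while most summits in the data lay near a TSS. That simulation therefore does not test the comparison of promoter summits with their flanks.

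The main set, tests, gene lists, motifs, naming rule and most alternatives were chosen before the data were examined. Chosen later were the aliases of renamed genes, the handling of microRNA transcripts, the added alternatives and part of the tests in the closing section. The rule named the 15 strongest peaks by the gene with the nearest TSS, bbx, up to 3 occupied members of each list by signal, the first 2 members without a summit in alphabetical order for lists past the threshold, and the 10 8-base sequences with the smallest p. The name pattern for eggshell genes also took Cp110 and Cp190, and the list was kept as fixed. Alternatives were the other thresholded set, IDR thresholds of 0.001 and 0.05, merged overlapping peaks, each replicate alone, TSS distances of 200 and 1000 bp, other ways of assigning summits to genes, other backgrounds and windows, and other measures of overlap. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.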

Results

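Chromatin immunoprecipitation with an anti-GFP antibody was used to ask where in the genome the fly protein encoded by bbx (bobby sox) sits during embryogenesis. The protein carries an HMG box, a DNA-binding fold shared with the SOX and TCF families, and was tagged with eGFP in transgenic Drosophila melanogaster. Embryos aged 0 to 24 h were collected as 2 biological replicates of 1 group, so the comparisons are between genomic sites, gene groups and sequences, and between the replicates. The conservative set of reproducible peaks, which is the set described unless another is named, held 4753 peaks. They formed 4470 separate regions that covered 1387 kb, or 1.01%, of the 7 chromosomes 2L, 2R, 3L, 3R, 4, X and Y. On their own, replicate 1 gave 4626 peaks and replicate 2 gave 3335. Peak signal ranged from 2.08 to 1502 with a median of 105. No read totals came with the peak lists, so the depth of each library is unknown here.

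By an overlap of at least 1 bp, most bbx peaks of each replicate had a partner in the other, most of all the strongest peaks. A peak of replicate 2 overlapped 2732 of the 4626 replicate 1 peaks (59.1%), and a peak of replicate 1 overlapped 2706 of the 3335 replicate 2 peaks (81.1%). With a reciprocal overlap of at least 50%, the share of replicate 1 peaks with a partner was 48.7%. The shared replicate 1 peaks had a median signal of 92.5 and the others 46.6. Sites found in both were promoter sites more often than sites found in 1 replicate: 91.4% of the shared replicate 1 peaks lay within 500 bp of a transcription start site (TSS), against 74.8% of the 1894 peaks of replicate 1 without a partner (Fisher's exact p = 1.91e-52). Replicate 2 split the same way, with 91.4% of its shared peaks near a TSS and 61.8% of the 626 others on the 7 chromosomes (Fisher's exact p = 5.67e-67). At the 4753 conservative peaks the signal of the replicates correlated with a Spearman rho of 0.770 and, on the log2 scale, a Pearson r of 0.849. Both values are across peaks, which are not independent replicates, so no p-value is given. The peaks had also been chosen by IDR for similar ranks in both replicates, and over all 103632 ranked peaks rho was 0.343. The tests were all two-sided. The median signal was 61.6 in the first replicate column and 49.0 in the second. The log2 ratio of the columns had a median of 0.32 and an SD of 0.51, and 91.6% of peaks differed by less than 2-fold. Peaks of replicate 2 shifted around each chromosome overlapped 1.36% ± 0.186 (SD over 1000 shifts) of the replicate 1 peaks, and the observed share lay above all of them (permutation p = 0.002, the smallest that 1000 draws can give).

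**Figure D1:**
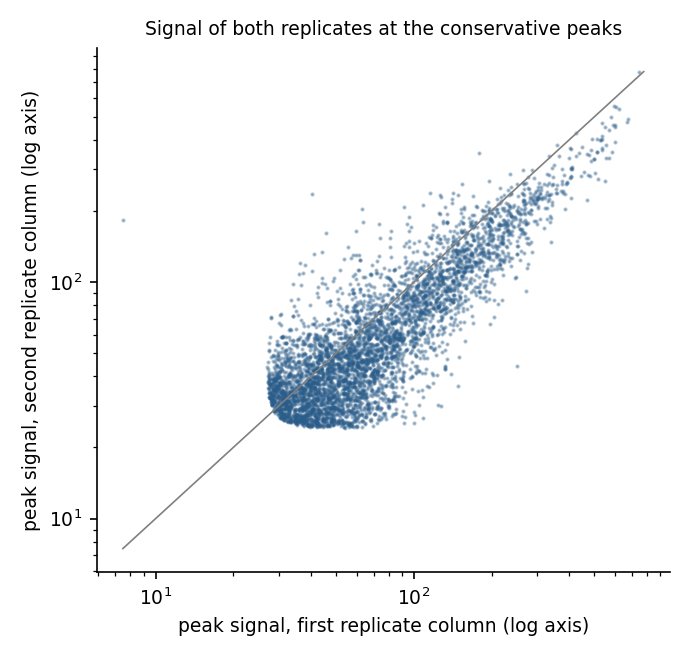
Peak signal in the second replicate column (y axis, log scale) against the first (x axis, log scale), 1 point per conservative peak, in the authors' signal units; the grey line marks equal signal. The points follow the line with a Spearman rho of 0.770, at peaks chosen by IDR for similar ranks, and lie mostly on the side of the first column, whose median was 61.6 against 49.0.

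Promoters held most of the sites. Of the 4753 summits, 3933 lay within 500 bp of an annotated TSS, a share of 82.7% (95% Wilson interval 81.6 to 83.8) that was 6.08 times the 13.6% ± 0.475 (SD over 1000 draws) of random positions on the same chromosomes. Replicate 1 alone gave 84.6% and replicate 2 alone 85.9%. The promoter summits sat close to the start site itself: 79.2% were within 100 bp of the nearest TSS, with a median offset of -19 bp and a middle range from -54 to 27 bp in the direction of transcription. The other classes held the rest, with smaller shares than random positions: coding exons (1.70% of summits against 13.8%), introns (8.46% against 39.4%), intergenic sequence (5.58% against 27.3%), 3' UTRs (0.884% against 4.4%) and exons of non-coding genes (0.231% against 0.818%). For 5' UTRs beyond 500 bp of a TSS the shares were 0.400% and 0.775%. That direction turned, without passing, at an IDR of at most 0.05 with no region left out (1.10-fold). The call also ended with replicate 1 alone and with the series' other thresholded set. The share of promoters passed its permutation test against random positions (adjusted p = 0.002, the smallest possible here). The shares add up to the whole, so the lower values of the other classes follow largely from the promoter share and are no separate evidence of avoidance. Summits moved by 5 to 20 kb, which stay in the same gene neighbourhoods, fell near a TSS in 20.4% of cases, and the fold over them was 4.06 (permutation p = 0.002).

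**Figure D2:**
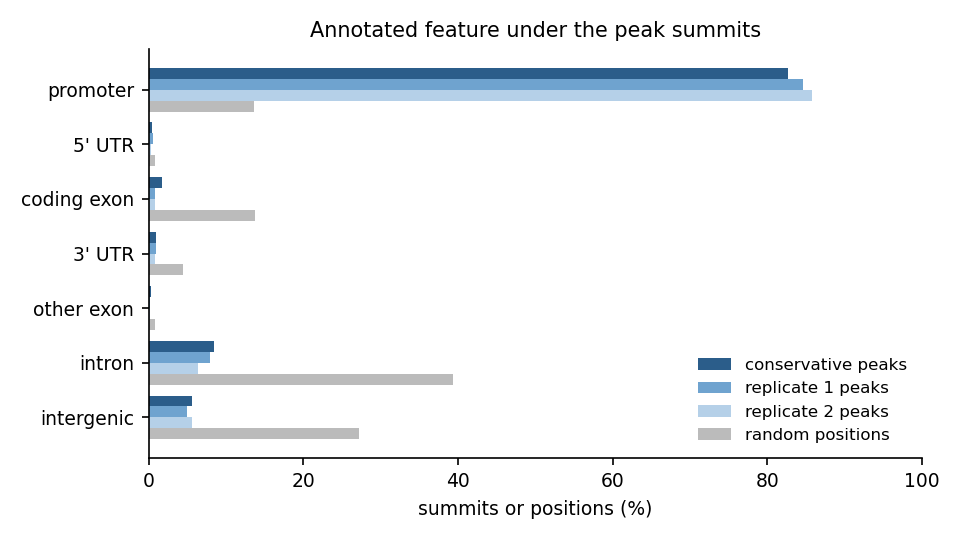
Share of summits (x axis, percent) in each annotated class (y axis) for the conservative peaks, for the peaks of each replicate and for random positions on the same chromosomes (mean of 1000 draws). Promoters took 82.7% of conservative summits against 13.6% of random positions, and the other classes, whose shares fall as that of promoters rises, lay below their random share.

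Peaks at promoters were also the stronger ones. The median signal was 117 at the 3933 promoter peaks and 75.1 at the 820 peaks farther from any TSS, a difference of 41.7 (permutation test with 100000 resamples, p = 1e-05, the smallest they can give). Within replicate 1 the medians were 67.7 and 47.7, and within replicate 2 they were 69.1 and 45.7. Peaks, not animals, were resampled here, so the p-value describes these peak lists.

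The 15 strongest sites were all at promoters. The highest signal, 1502 in the pooled reads and 760 ± 23.1 (SD, n = 2) in the replicates, was at the peak on 2R from 21501827 to 21502192, whose summit was -61 bp from the TSS of MESK2. Next came Ube3a, which encodes a ubiquitin ligase (3L, 11210426 to 11210827; pooled signal 1182; 582 ± 60.5, SD, n = 2), and RpL32, a protein of the large ribosomal subunit (3R, 30046062 to 30046413; 1154; 579 ± 40.7, SD, n = 2). Pym, whose product binds the exon junction complex, had a pooled signal of 1149 at 2R, 23856785 to 23857109. Daxx, named for a histone chaperone, had 1147 at 2L, 6480721 to 6481030, and the proteasome lid gene Rpn6 had 1145 at 2R, 14752191 to 14752571. The remaining sites, with pooled signals from 948 to 1067, were at the TSSs of Capr, CG2924, jagn, the small ubiquitin-like modifier gene Sumo, Creld, Pcif1, the succinyl-CoA synthetase gene Scsalpha1, RhoGAP93B and the chaperone gene Hsp110. Their replicate means ran from 476 ± 86.5 at Hsp110 to 539 ± 56.1 at Capr (SD, n = 2). The summits of the 15 sites lay between -96 and -12 bp from the nearest TSS. The octamer TATCGATA, known as the DNA replication-related element or DRE, lay within 100 bp of the summit at Pym, Sumo, Creld, Scsalpha1 and Hsp110.

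Peaks lay in the tagged gene itself, from its first TSS to position 21369976. bbx lies on X from 21363028 to 21373145 on the plus strand, over the same span as the gene waw, and has 4 annotated TSSs. Its span and the 500 bp to either side held 7 summits, 5 of them within 500 bp of a bbx TSS. Of these, 2 belonged to peaks that overlapped a stronger one, with the same replicate values and a lower pooled signal, and 3 summits near a TSS were left when overlapping peaks were merged. Replicate 1 alone had 4 summits near a bbx TSS and replicate 2 alone had 1. The strongest had a pooled signal of 99.3 (48.2 ± 0.580 in the replicates, SD, n = 2) at 21367822, and the next 95.5 (50.6 ± 7.61, SD, n = 2) at 21369600. At the first TSS the summit at 21363085 had a signal of 79.0. Further peaks lay in a 5' UTR at 21365069 (68) and in an intron at 21366820 (62.6). These values were below the median of all promoter peaks, 117. Ranked peaks of the gene away from TSSs had a median signal at percentile 98.9 of stretches of the same length on X, which extra copies of the locus on the transgene would also give, so binding and extra copies were not told apart.

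**Figure D3:**
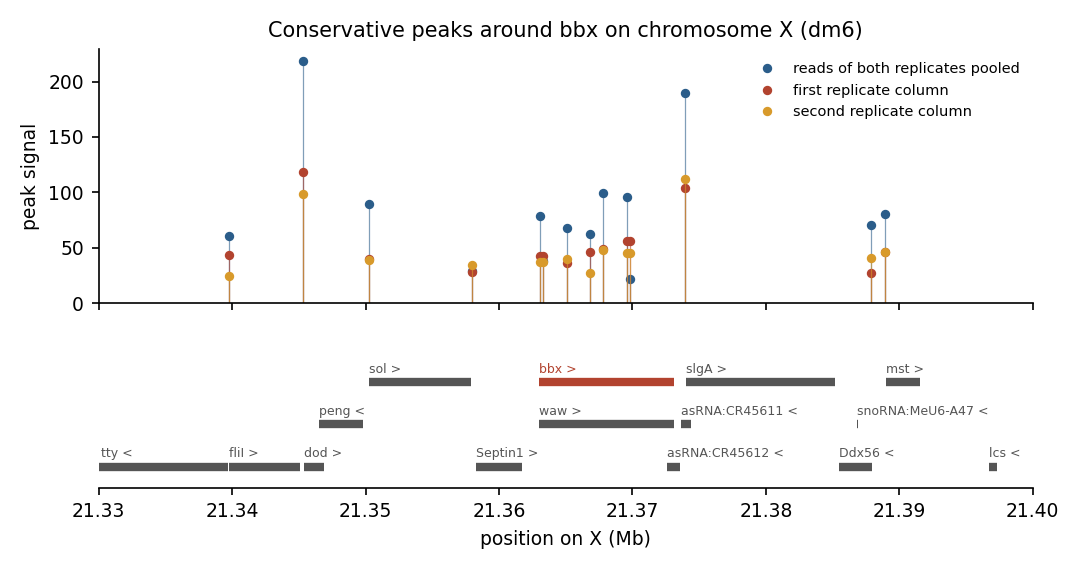
Conservative peaks around bbx on X (dm6), with position in Mb on the x axis and signal on the y axis, for the pooled reads and for each replicate column; the lower part shows the genes, with arrowheads for their strand. The strongest peak within bbx had a pooled signal of 99.3, and the highest peak drawn, 218, lay outside the gene.

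Genes of the basic machinery of protein synthesis, energy supply and cell division were occupied more often than other genes. Of all 13968 protein-coding genes, 4304 (30.8%) had a summit within 500 bp of a TSS. Among the spliceosome genes this held for 20 of 28 (71.4%), with SmD3 (pooled signal 767), SmE (529) and Sf3a1 (447) highest and Prp19 and Prp31 without a summit. Of the cytoplasmic ribosomal protein genes, 64 of 92 (69.6%) had one, led by RpL32, RpS2 (930) and RpS30 (575), while RpL10 and RpL10Aa had none. The mitochondrial ribosomal protein genes reached 46 of 73 (63.0%), with mRpL4 (662), mRpL17 (616) and mRpL33 (558) first and mRpL13 and mRpL14 among those without. Cell cycle and replication genes gave 25 of 40 (62.5%). CycB (483), E2f2 (339) and Cdk2 (329) had the highest signals of that list, and Cdc45 and Cdk1 had no summit. Proteasome genes gave 27 of 48 (56.3%), led by Rpn6, Prosalpha7 (822) and Rpn10 (558), with none at Prosalpha1 or Prosalpha1R. Translation factor genes gave 26 of 52, led by eIF3f1 (773), eIF3a (671) and eIF2gamma (607), with none at eEF1alpha2 or eEF5. Oxidative phosphorylation genes gave 41 of 87 (47.1%), led by UQCR-14 (590), COX7A (490) and ATPsynCF6 (477), with none at ATPsynC or ATPsynCF6L. Each of these lists passed Fisher's exact test with Benjamini-Hochberg adjustment over the 29 lists, from an adjusted p of 1.06e-13 for the cytoplasmic ribosomal protein genes to 0.00816 for the translation factors. The translation factor call ended when each summit was assigned to its nearest gene alone (adjusted p = 0.135 by Fisher's exact test), and that of the oxidative phosphorylation genes at an IDR of at most 0.001 (0.0676).

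Insulator and architectural protein genes and genes for parts of 3 signalling pathways were also occupied more often than the rest. So was the list of HMG-box genes, which holds bbx itself. The insulator and architectural list also held the transcription factor genes Dref and zld, both with a summit. Among insulator and architectural protein genes, 11 of 16 (68.8%) had a summit (Fisher's exact adjusted p = 0.00443), with BEAF-32 at a pooled signal of 458 (244 ± 39.1, SD, n = 2), pita at 376 and CTCF at 305; Chro and Clamp had none. BEAF-32 encodes a boundary protein that recognises CGATA sequences. Of the HMG-box genes, 9 of 15 had one, bbx among them (Fisher's exact adjusted p = 0.0358). Sox14 (470), pan (361), the fly TCF gene, and Sox102F (105) were the highest, and HmgD and Sox100B had none. Without bbx, 8 of 14 had one, and the fold over other genes went from 1.95 to 1.86 and no longer passed (Fisher's exact adjusted p = 0.0616). The call ended under 7 of 13 alternatives in all, with adjusted p-values up to 0.447 in the exact or permutation tests. Wnt pathway genes gave 15 of 26 (57.7%), with the receptor gene fz3 (364), pan and the corepressor gene gro (228) first and Apc2 and Wnt10 without a summit. EGFR and Ras pathway genes gave the same 15 of 26, with the ligand genes Krn (362) and vn (163) and the protease gene rho (150) first and Cbl and Dsor1 without. Both had an adjusted p of 0.00886 by Fisher's exact test, and at an IDR of at most 0.001 the EGFR and Ras call ended. Notch pathway genes gave 13 of 24 (54.2%; Fisher's exact adjusted p = 0.0367), led by the ubiquitin ligase gene mib1 (388), the coactivator gene mam (378) and Su(H) (307), with none at E(spl)m2-BFM or E(spl)m4-BFM. The Notch call ended under 4 of 12 alternatives, with adjusted p-values up to 0.447 in the exact or permutation tests.

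Transfer RNA genes were the largest group with frequent peaks. Of 290 tRNA genes, 178 (61.4%) had a summit within 500 bp, against 25.3% of all other genes (Fisher's exact adjusted p = 4.06e-36), and the replicates alone gave 54.8% and 62.1%. Many tRNA genes sit in clusters and share a summit: 140 peaks accounted for them. The highest signals were at tRNA:Leu-AAG-1-3 (509), tRNA:Gly-TCC-1-2 (505) and tRNA:Glu-CTC-2-3 (404), and tRNA:Ala-AGC-1-1 and tRNA:Ala-AGC-2-5 had none. The first of these summits was also that of snoRNA:U3:54Ab. Small nuclear RNA genes did not pass the test against the rest (8 of 32, 25.0%; Fisher's exact adjusted p = 1), although snRNA:7SKa (669), snRNA:U6:96Ac (406) and snRNA:U2:34ABb (174) carried peaks.

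Of the fixed lists, 7 had a summit less often than other genes. They were those of cuticle proteins, olfactory and gustatory receptors, antimicrobial peptides, eggshell and yolk proteins, histones, microRNAs and snoRNAs. The receptor, antimicrobial peptide and eggshell lists had been chosen beforehand for tissues or conditions other than a normal embryo. Expression was not measured here, so they cannot tell inactive genes from genes that the protein avoids. Such genes are also part of the other genes that each protein-coding list was compared with. Of 116 cuticle protein genes none had a summit within 500 bp, which allows a share of up to 2.59% (Fisher's exact adjusted p = 5.55e-18); Ccp84Aa and Ccp84Ab are examples. Of 120 olfactory and gustatory receptor genes only Gr97a (82.8) had one (0.833%; Fisher's exact adjusted p = 3.57e-17), so that Gr10a and Gr10b had none. Antimicrobial peptide genes gave 1 of 20, the gene AttD (228), with none at AttA or AttB. Among the genes taken for eggshell and yolk, 1 of 16 had a summit. That gene was Cp190 (179), an insulator gene that the name pattern had caught together with Cp110, and the chorion gene Cp15 and the other members had none. The adjusted p-values of these lists were 0.0217 and 0.0451 by Fisher's exact test. The antimicrobial call ended under 4 of 12 alternatives, with adjusted p-values up to 0.253 in the exact or permutation tests, and the eggshell call under 6 of 13, up to 0.355. Histone genes had a summit in 3 cases (2.61%; Fisher's exact adjusted p = 7.97e-14), namely His2Av (282), His4r (114) and His3.3A (107), which lie outside the repeated histone cluster; His1:CG31617 and His1:CG33801 had none. Reads from near-identical histone copies are hard to place, so the count for the cluster is uncertain. MicroRNA genes (15 of 260, 5.77%; Fisher's exact adjusted p = 2.25e-16) and snoRNA genes (33 of 269, 12.3%; Fisher's exact adjusted p = 1.75e-07) also lay below other genes. The highest microRNA signals were at mir-3645 (393), mir-995 (329), whose summit was also that of Cdk2, and mir-9370 (292). The highest snoRNA signals were at snoRNA:U3:54Ab (509), snoRNA:Psi18S-176 (436) and snoRNA:Me18S-A1576 (403), and mir-1, mir-10, scaRNA:MeU1b-A234 and scaRNA:MeU2-48 had no summit. The snoRNA call ended with a distance of 1000 bp (Fisher's exact adjusted p = 0.839). For the microRNA and snoRNA lists the TSS was the annotated start of the short RNA or its precursor. A promoter of a longer host transcript farther than 500 bp away was not counted, so these low shares do not show unoccupied promoters.

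Lists of embryonic patterning and tissue genes did not pass the test against other protein-coding genes, although many single members were occupied. The counts were 4 of 8 Hox genes, 13 of 28 segmentation genes, 9 of 23 dorsoventral patterning genes, 9 of 26 neuroblast and neural genes, 5 of 24 muscle and mesoderm genes, 9 of 19 germ line and piRNA genes, 10 of 24 Polycomb and trithorax group genes and 8 of 20 heat shock genes. Their adjusted p-values by Fisher's exact test ran from 0.136 for the segmentation genes to 0.698 for the neural genes. Among the Hox genes, peaks lay at abd-A (216; 112 ± 12.9, SD, n = 2), Ubx (197; 89.7 ± 37.9) and Abd-B (63.5; 34.7 ± 8.12). The strongest segmentation and germ line gene was nanos, the posterior determinant, at a pooled signal of 820 (412 ± 93.6, SD, n = 2), followed by odd (138) and hry (117) and, in the germ line list, by tej (393) and tud (298). Within 200 bp of a TSS, nanos and tej had no summit. Other occupied regulators were rho, ush (118) and tup (116) of the dorsoventral list, brat (248), pros (155) and insc (136) of the neural list, and Mef2 (261), Tm1 (189) and tin (120) of the mesoderm list. Scm (382), Asx (300) and Pc (262) led the Polycomb list, and DnaJ-1 (419), Hsp83 (184) and Hsc70-5 (178) the heat shock list. Counting a summit anywhere in the gene as well as near its TSS put the Hox, germ line and Polycomb lists past the threshold. The Polycomb list passed under 4 of 12 alternatives, the series' other thresholded set among them, with adjusted p-values from 0.0125 to 0.670 in the exact or permutation tests. The segmentation list passed under 2 of 12, replicate 2 alone and nearest gene alone, from 0.0376 to 1.

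**Figure D4:**
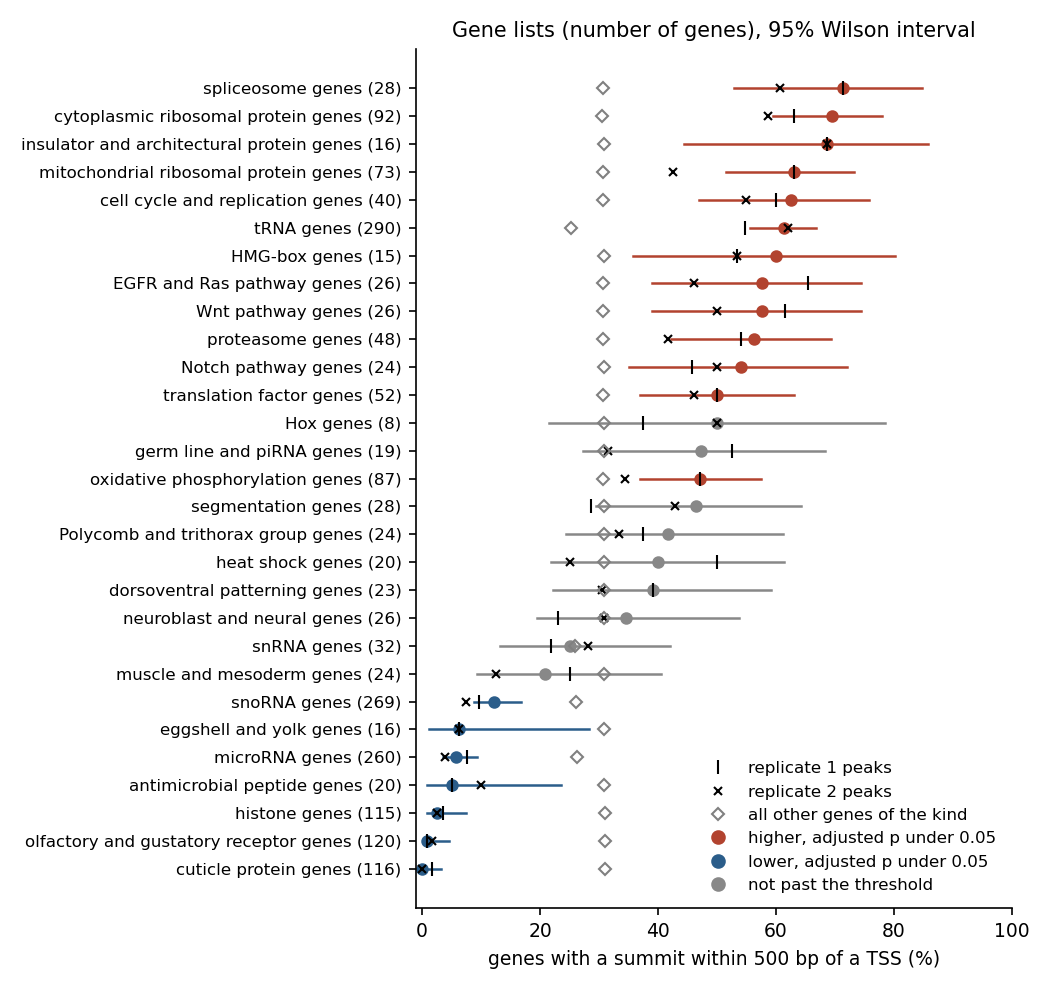
Share of genes with a summit within 500 bp of a TSS (x axis, percent) for each fixed gene list (y axis, number of genes in brackets); points and lines give the conservative peaks with 95% Wilson intervals, black marks the peaks of each replicate, and open diamonds all other genes of the same kind. Spliceosome genes (71.4%) and cytoplasmic ribosomal protein genes (69.6%) stood highest, and cuticle protein genes (0 of 116) lowest.

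Of the 30 motifs, the one with the smallest p against the flanks was the DRE, TATCGATA, a promoter element bound by the transcription factor DREF and overlapping the sites of BEAF-32. It lay within 100 bp of 834 of the 4753 summits (17.5%, 95% Wilson interval 16.5 to 18.7) and in 32 flanking windows 1000 bp away (0.673%), a 26.1-fold difference; the replicates alone gave 18.2% and 22.5%. Other elements of constitutively active promoters followed: Motif 1, bound by M1BP, in 4.02% against 0.337%, with its core GGTCACAC in 7.26% against 0.694%; Motif 7 in 13.0% against 2.23%; Motif 5 in 3.22% against 0.274%; and Motif 6 in 1.26% against 0.147%. The CTCF element (2.38% against 0.715%), the GAGA element (6.71% against 3.39%) and the longer GA repeat (1.70% against 0.778%) were also more frequent at summits, as were the CACGTG E-box (4.19% against 2.57%), the Initiator (20.9% against 17.4%) and the MTE (0.337% against 0.0842%). The core recognised by HMG-box proteins of the SOX and TCF type, WWCAAWG, was less frequent at summits than in the flanks (950 windows against 1182), and longer SOX, TCF and Capicua elements did not pass the test. The Bicoid (4.27% against 7.15%), Snail E-box (6.73% against 9.78%) and CATATG (3.53% against 4.80%) elements were also lower. In all, 12 of 30 motifs were higher and 4 lower in exact sign tests, with adjusted p-values of 1.18e-205 for the DRE, 2.42e-92 for Motif 7 and 4.5e-08 for the HMG core. The other 14 did not pass, among them the elements of Zelda and PHO. The TATA box passed as higher under 5 of 11 alternatives, the STAT and homeodomain elements passed as lower under 4 of 11 each, AP-1 and EWG passed as higher under 2 each, the longer SOX element as lower and Su(Hw) as higher under 1 each, and Dorsal turned and passed against shuffled windows (1.73-fold). The CACGTG and Snail E-box directions turned against summit windows shuffled with their dinucleotides kept (0.896-fold and 1.23-fold). CACGTG did not pass there. The MTE and GA repeat calls ended without replicate 1.

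Against promoters without a peak, the occupied promoters held the DRE and Motif 7 more often and the TATA box and Initiator less often. Windows at 3929 promoter summits held the DRE in 20.3% of cases, against 1.86% of windows at the same offset from TSSs without a summit, and Motif 7 in 14.4% against 3.82%. The TATA box, a hallmark of tightly regulated promoters, was found in 3.39% against 8.02%, and the Initiator in 840 windows against 1176, the reverse of the Initiator's direction against flanks. Motif 6, the MTE and the GA repeat, which had passed against flanks, did not pass here (exact sign tests, adjusted p = 0.479, 0.479 and 0.0552). The exact sign tests gave adjusted p-values of 5.95e-160 for the DRE, 9.92e-61 for Motif 7, 7e-18 for the TATA box and 2.03e-17 for the Initiator. The 820 peaks farther than 500 bp from a TSS held the DRE in 4.39% of windows against 1.71% of their flanks, the GAGA element in 11.6% against 4.27% and the CTCF element in 5.85% against 0.976% (exact sign tests, adjusted p = 0.0112, 9.79e-07 and 6.88e-07). The call for the HMG core ended there (169 windows against 210, exact sign test adjusted p = 0.0506). Those for the Motif 1 core, Motif 5, Motif 6, the MTE and the Snail E-box ended too (exact sign tests, adjusted p from 0.103 to 0.953).

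**Figure D5:**
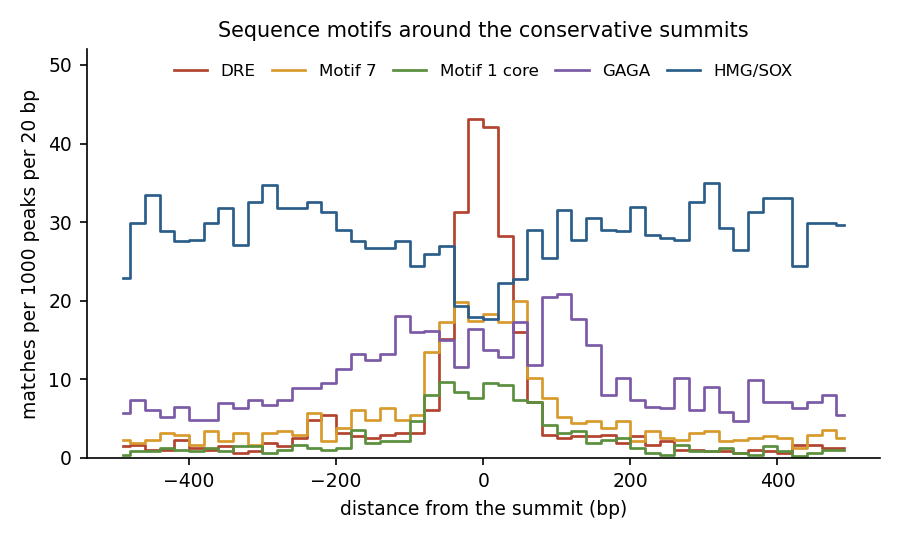
Matches of 5 motifs per 1000 conservative peaks in bins of 20 bp (y axis) by distance from the summit (x axis, bp). The DRE peaked at the summit with 43.1 matches per 1000 peaks in the bin from -20 to 0 bp, while the HMG core was lowest in the next bin, from 0 to 20 bp.

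A search over all 8-base sequences, with no list of motifs, ranked the DRE first. It used the same windows and test as the motifs, so its DRE count is the same one and no separate evidence. Of 32896 sequences, 1278 were more frequent at summits and 1483 in the flanks (exact sign tests with Benjamini-Hochberg adjustment). The 10 with the smallest p-values each contained CGATA on one strand: TATCGATA, ATCGATAG (815 summits against 34 flanks), ATCGATAA (638 against 53), ATATCGAT (610 against 51), ACTATCGA (450 against 23), AATCGATA (504 against 43), GTTATCGA (401 against 26), GCTATCGA (393 against 27), CATCGATA (403 against 40) and ATCGATAC (318 against 18). The adjusted p of the last was 5.71e-70 by the exact sign test.

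Peaks were spread over the chromosomes with 3 exceptions. Arm 2R had 1050 peaks, or 41.5 per Mb, against the 877 its length predicts (exact binomial adjusted p = 8.76e-10). The small chromosome 4, which is largely heterochromatic, had 28 peaks, 0.607 times the prediction (exact binomial adjusted p = 0.014), and Y had none of the 118 expected (exact binomial adjusted p = 1.63e-51). The densities of 2L, 3L, 3R and X, between 32.8 and 36.7 per Mb, did not pass the test. At an IDR of at most 0.05 with no region left out, 2L, 3R and X passed, 3R in the other direction (1.07-fold), and at an IDR of at most 0.001 3L passed. With the number of TSSs in place of length, the excess on 2R was smaller but still passed (1.08-fold, exact binomial adjusted p = 0.029). The call for chromosome 4 ended with the number of TSSs in place of length, or with replicate 1 alone. Much of Y is repetitive, where short reads are hard to place, so the count on Y is no measure of occupancy there.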

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

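The tests of base composition at the DRE and of extra copies of bbx were chosen only after the result was seen. The ranked list of the 2 replicates held 4929 peaks past the IDR threshold, and 176 of them were absent from the conservative set, which stood out as signal in peaks that the comparisons had not used. Of these, 105 lay on 3R, 43 on 2L and 10 on 2R, their median signal was 103, and 110 of the 168 on the chromosomes (65.5%) lay within 500 bp of a transcription start site. The highest of the 168 had a pooled signal of 947 and 470 ± 110 in the replicates (SD, n = 2). A further 8 were on scaffolds outside the 7 chromosomes, 6 on a Y scaffold and 2 unplaced, with a highest signal of 1093 (558 ± 230, SD, n = 2). The reason for their absence is not given in the sources used here.

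Of the 30 motifs, the DRE had the smallest p against the flanks. Base composition was argued against, since 834 summit windows held the DRE against 19 of the same windows shuffled with their dinucleotides kept, 43.9-fold (95% interval 29.8 to 76.0). A location at annotated promoters of any kind was argued against too. Promoter summits held the DRE 10.9 times (8.86 to 13.8) as often as windows at the same offset from TSSs without a summit. The windows without a summit held the TATA box more often (8.02% against 3.39%), so these promoters differed in more than the summit. A location at promoters of a certain kind was therefore not argued against. The design has 1 group, so no biological explanation was tested, here or for the patterns that follow. Whether the tagged protein touches the DRE or is held there by another protein stays open. Enrichment of highly transcribed promoters by the assay itself stays open too, for the DRE, promoter and gene list results, since no untagged sample was used.

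Peaks at tRNA genes were frequent. Of the 52 tRNA genes without an identical copy, 24 had a summit (46.2%, 33.3 to 59.5), above the 25.3% of other genes. Genes with such a copy reached 64.7%. A summit within 500 bp can belong to a neighbouring tRNA gene that has copies, and only exact copies were counted. These shares therefore cannot decide whether reads shared between gene copies gave the peaks. Neighbouring protein-coding promoters were argued against as the whole cause. The share was 57.3% (50.6 to 63.8) among the 211 tRNA genes with no protein-coding TSS within 1000 bp, although it was 72.2% among the 79 with one. With no untagged sample used here, enrichment of highly transcribed genes by the assay itself stays open.

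Peaks lay in bbx, the gene that the transgene carries. Extra copies of the locus may raise the signal there: the median signal of its 13 ranked peaks away from TSSs was 29.1, at percentile 98.9 of stretches of the same length on X, whose median was 16. Binding throughout the gene would give the same value, so both stay open. The many TSSs of bbx cannot be told apart from these, since 5 of its 7 summits (71.4%, 35.9 to 91.8) were near a TSS against 85.2% on X, and 7 summits are too few.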

How the results depend on the processing

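The alternatives at an IDR of at most 0.001 or 0.05, without pooled peaks below both replicates, without Cp110 and Cp190 in the eggshell list, and without bbx in the HMG-box list were chosen only after the result was seen. An IDR of at most 0.01, set beforehand as a stricter threshold, equals the deposited threshold, so it tests nothing. Promoter location kept its direction and call under the other alternatives (69.1 to 91.8% of summits), and so did the signal difference at promoters (19.9 to 47.2). The number of lists past the threshold ran from 14 to 23. Without 1 replicate, the number of peaks was 3335 to 4626, the promoter share 84.6 to 85.9%, the signal difference 19.9 to 23.4, lists past the threshold 17 to 19, motifs 14 to 19, chromosomes 2 to 3, classes 6 to 7 and 8-base sequences 2058 to 2895. The number of peaks was 2748 at an IDR of at most 0.001, since fewer pass by construction. At an IDR of at most 0.05 with no region left out it was 7371, and 6 chromosomes passed. The directions of 5' UTRs (1.10-fold, not past the threshold) and 3R (1.07-fold) turned there. Spearman's rho was 0.343 over all ranked peaks, which were not chosen by IDR. Only 1117 8-base sequences passed with a window of 50 bp, where windows hold fewer bases. Against shuffled windows the directions of CACGTG (0.896-fold), the Snail E-box (1.23-fold) and Dorsal (1.73-fold) turned, and CACGTG did not pass there. Against TSSs without a peak those of the TATA box (0.422-fold) and Initiator (0.714-fold) turned. Over the 820 peaks away from TSSs, 9 motifs passed. Motif 1 (0.667-fold, 2 windows against 3), the Initiator (0.981-fold, 151 against 154) and CATATG (1.05-fold, 44 against 42) turned without passing. Counts this close show a lost call and no reversal. Where no construction is named, the cause was not tested. Of 350 gene list values, 317 kept their side of the threshold, 25 lost the call and 8 gained it. Of 330 motif values, 289 kept it, 14 lost it, 19 gained it and 8 turned. Of 1044 values for named genes, 39 changed. With a distance of 200 bp, 11 named genes lost their summit near a TSS. These were AttD, Gr97a, Hsp83, Sox14, mRpL17, mRpL33, mir-9370, mir-995, nanos, snoRNA:U3:54Ab and tej. Read depth is unknown, so a gene without a summit may still be bound below the IDR threshold.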

Other observations

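The comparisons in this part, the DRE by peak strength, at tRNA genes and beside Motif 1, and the pooled peaks below both replicates, were chosen only after the result was seen. The DRE, the promoter element bound by DREF, became more frequent with the strength of the peaks. It lay within 100 bp of the summit in 37.5% of the 1188 peaks with the highest signal, and in 21.0%, 8.59% and 3.11% of the next 3 groups of the same size or 1 more. The share of promoter peaks went from 96.5% in the strongest group over 88.0% and 79.0% to 67.5% in the weakest. Peaks with a DRE had a median signal of 197, and those without one 94.8, a difference of 102 (permutation test, two-sided, p = 1e-05, the smallest that 100000 resamples can give). Peaks found in both replicates held the DRE more often than peaks found in 1. The shares were 26.1% against 6.86% in replicate 1 (Fisher's exact test, two-sided, p = 6.31e-69). In replicate 2 they were 26.1% against 7.03% (p = 1.13e-29 by the same exact test). Peaks found in both were also stronger and more often at promoters. Promoter location was held fixed in none of these tests, nor peak strength in those of shared peaks, so they are not separate evidence.

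The sites at tRNA genes, which RNA polymerase III transcribes, seldom held the DRE. The 140 peaks within 500 bp of a tRNA gene had a median signal of 168. Only 2 of them (1.43%) held a DRE, against 796 of the 3793 other promoter peaks (21.0%; Fisher's exact test, two-sided, p = 1.05e-11, odds ratio 0.0546). The core of Motif 1, the element of M1BP, lay in 9.11% of peaks with a DRE and 6.86% of those without (odds ratio 1.36, Fisher's exact test, two-sided, p = 0.0272). Promoter peaks made up 798 of the 834 peaks with a DRE and 3135 of the 3919 without. The core lay in 1.22% of the 820 peaks over 500 bp from a TSS and 8.81% of the 3793 promoter peaks without a tRNA gene. Location at promoters was not held fixed in the test, so it cannot tell a link between the elements from shared promoter location. Promoter summits had start sites on both strands within 500 bp in 1293 cases (32.9%), against 24.7% of the 23246 annotated TSS positions, a difference that was not tested.

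Of the conservative peaks, 245 (5.15%) had a pooled signal below that of both replicates, and 244 of these lay within 500 bp of a stronger summit, at a median distance of 202 bp.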
